A study of Homo sapiens with 16 samples.

How the data were processed

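Messenger RNA from OVCAR3, an established human ovarian carcinoma line, was measured on Affymetrix oligonucleotide arrays. 12 U133A arrays held 4 groups of 3 biological replicates, namely ethanol vehicle and 8, 24 and 72 h with 1,25-dihydroxyvitamin D3 (1,25(OH)2D3). 4 U95 arrays held 1 sample for each of the same times. All 16 arrays were matched to their labels, and 0 columns of the tables were left unmatched.

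The deposited values are an intensity per probe set, the MAS5 signal per the submitters' processing notes, which give no version. They are on a linear scale, and the 2% trimmed mean was 500.2 on every array, from which a scaling of each array by the authors to a common mean was read. The values were therefore used as deposited. Detection calls were not used here. Probe sets were assigned to genes with the platform annotation, and gene names and gene order were taken from RefSeq on assembly GRCh38.p14. Of 22283 U133A probe sets, 19071 had exactly 1 gene, 1043 had several and 2169 were not listed, 68 of them controls. The U95 type had 12626 probe sets, of which 10961 had exactly 1 gene.

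In R 4.3.3 with the data.table package, version 1.17.8, the values were transformed as log2(value + 15.833), where 15.833 is the 10th percentile of all U133A values. The corresponding number for the U95 values was 13.87. The probe set with the highest mean stood for each gene, which gave 11963 genes on U133A, 4310 of them with several probe sets. Genes whose mean over all 12 arrays lay under the 40th percentile were left out, which left 7178. A linear model with 1 term per group was fitted to all 12 arrays with limma 3.58.1 (eBayes with trend), so that the groups share 1 estimate of the spread with 8 residual degrees of freedom. Adjusted p values are Benjamini-Hochberg values over the 7178 genes, with a threshold of 0.05. The contrasts were each time against vehicle, the mean of the 3 treated groups against vehicle, an F test of any time, and the differences between times. The fit reported has no replicate block. Deviations of same-number arrays from their group means correlated over 0.1 in all 3 pairs from 8 to 24 h (0.108 to 0.157) and from 24 to 72 h (0.103 to 0.187). In the other 4 comparisons 1 or 2 of 3 pairs did. All 18 same-number correlations were positive (lowest 0.052), so the numbers may pair the arrays in every comparison. That reading comes from the data and the design, since no label states it, and the fit reported leaves it out. Counts with a replicate block are given as an alternative. The weights of the alternative with array weights used statmod 1.5.0. The number of arrays limits the precision.

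The comparisons, tests, gene lists, the rule for naming genes and the alternatives were chosen before the data were examined. There were 31 gene lists written from textbook knowledge. They covered vitamin D receptor targets, vitamin D metabolism and receptor complex, death receptor apoptosis, mitochondrial apoptosis, G1 phase, DNA replication, mitosis, p53 targets, interferon response, NF-kappaB and cytokines, cholesterol synthesis, fatty acid metabolism, steroid receptors, the EGF receptor family, the insulin-like growth factor axis, TGF-beta signalling, epithelial junctions and Wnt, mesenchymal and invasion genes, immediate early genes, the unfolded protein response, heat shock proteins, glycolysis and hypoxia, oxidative stress defence, ribosomal proteins, mitochondrial respiration, the proteasome, ovarian carcinoma markers, keratins and squamous differentiation, and markers of fibroblasts, leukocytes and endothelial cells. The 29 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each contrast. Each was also tested with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone.

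Named genes were, for each time, the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose 3 treated values all lay beyond all 3 vehicle values. Where fewer than 5 passed, the genes with the lowest p filled up to 5. Added to these were up to 4 members with the lowest p of each list described, and GADD45A, CYP24A1 and VDR throughout. For differences between times, the 5 genes with the lowest p in each direction were named. Other names are said to have been chosen after their values were seen.

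The U95 arrays have no replicates, so no test between arrays was made. For each time, the log2 ratio to the U95 vehicle array was computed for the 4167 genes above the filter on both array types, and the median of each set of U133A calls was placed among 10000 random gene sets matched on mean expression, as were the medians of the gene lists. These percentiles compare genes with genes and hold no spread between arrays. The overlap of calls between times was set against independent lists and 100 simulations of unchanged groups with the same vehicle arrays, by their calls and by as many genes of highest rank.

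The alternatives were quantile normalization, median centring, a pseudocount of 1 or of 4 times the 10th percentile, no filter and a filter at the 60th percentile, every probe set on its own, the mean of a gene's probe sets, no probe sets of the x or s type, eBayes without trend or with robust estimation, array weights, a replicate block, a log2 change of at least 1, an adjusted p of 0.1, only the groups compared, other list tests, and leaving out each array in turn. Where an array was left out, its group held 2, and the spread came from all groups.

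The same fit was tested on simulated data with the design of the 12 arrays, in 10 runs of 7178 genes with 200 changed. At 24 h it recovered 39.3% of changes of 0.5 on the log2 scale, 87.8% of changes of 1 and 99.4% of changes of 2, with a mean of 7.2 calls among 6938 unchanged genes. At 8 and 72 h it recovered 87.2% and 87.9% of changes of 1, with a mean of 8.2 and 7.9 such calls. A list of 40 genes shifted by 0.3 was called in 10 of 10 runs, and an unshifted list in 0. The simulated genes varied independently of one another, and these list p values were not adjusted. The runs therefore cannot show how often correlated genes lead to false list calls.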

Results

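The study asked which genes 1,25(OH)2D3, the hormonal form of vitamin D, changes in OVCAR3 ovarian carcinoma cells. The hormone acts through the nuclear vitamin D receptor, VDR. Additions were staggered over 72 h so that cells with 8, 24 or 72 h of hormone and vehicle cells were harvested together, after equal exposure to ethanol. The labels give the dose as 0.1 pM, and the arrays cannot check that unit. An initial set of 4 U95 arrays, 1 for each time, had drawn the study to GADD45, a growth arrest gene. Before the 12 U133A arrays, made from 3 independent experiments, the cells' response was tested by Northern blot for GADD45.

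The median signal of the U133A arrays lay between 168 and 196, and the 10th percentile between 13.4 and 17.7. Correlations between arrays on the log2 scale ran from 0.958 to 0.976. The log2 ratio of 3' to 5' control probe sets lay between 0.048 and 0.24 for ACTB and between -0.18 and 0.042 for GAPDH, and for ACTB it was 0.094 ± 0.070 at 72 h and 0.17 ± 0.086 in vehicle (mean ± SD, n = 3; not tested). Fibroblast, leukocyte and endothelial markers had median signals of 103, 104 and 40.6 in vehicle, which cannot be set against those of other genes, since signals are not comparable between probe sets. The 5 fibroblast markers that could be tested did not differ as a list (camera adjusted p = 0.25, 0.70 and 0.92 at 8, 24 and 72 h). None of the 2 leukocyte markers and the 1 endothelial marker above the filter passed.

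After 8 h, CYP24A1, CAMP and GADD45A were among the genes higher than in vehicle. Folds and log2 changes were computed on values with 15.8 added, so where 1 of the signals is low they depend on that number and give no exact ratio. CYP24A1, the mitochondrial enzyme that breaks down 1,25(OH)2D3, rose 50.0-fold, from a signal of 129 ± 103 to 6185 ± 380 (mean ± SD, n = 3; log2 change 5.65, SE 0.33, adjusted p = 1.6e-07). CAMP, which encodes the antimicrobial peptide cathelicidin, rose from 30.8 ± 3.63, a signal near background, to 338 ± 106 (log2 change 2.87, or 3.36 and 2.05 with a pseudocount of 1 and of 4 times the 10th percentile, adjusted p = 8.5e-07). GADD45A rose 2.81-fold from 468 ± 89.8 to 1332 ± 107 (adjusted p = 3.5e-05). RGCC, a regulator of the cell cycle, fell from 1355 ± 152 to 283 ± 35.4, a log2 change of -2.20 (SE 0.20, adjusted p = 1.4e-05). VDR had a signal of 414 ± 60.8 in vehicle and 480 ± 65.6 at 8 h and did not pass (log2 change 0.21, adjusted p = 0.98), and the other VDR probe set above the filter had the opposite sign.

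In all, 51 of 7178 genes rose and 4 fell at 8 h, 17 and 2 of them by at least 2-fold. The other largest rises were PALMD (log2 change 1.93), SECTM1 (1.68), the transcription factor GATA6 (1.60), DUSP10, a phosphatase of stress kinases (1.54), the calcitonin-family peptide CALCB (1.51), the death ligand TNFSF10, also called TRAIL (1.46), and the cyclic AMP sensor RAPGEF3 (1.43). The other falls were IRF8, a transcription factor of the interferon regulatory factor family (-1.07, adjusted p = 0.011), the secreted protease ADAMTS1 (-0.85, adjusted p = 0.039) and LMCD1 (-0.73, adjusted p = 0.0056). NAV2 came next with -0.57 and did not pass (adjusted p = 0.051; 0.042 with a replicate block). The number that fell was 15 with a replicate block. Without 8 h replicate 1, SECTM1 and RAPGEF3 no longer passed (adjusted p = 0.056 and 0.097). The call of IRF8 ended without vehicle replicate 1 or 3 or 8 h replicate 2, and that of ADAMTS1 without any 1 of the vehicle and 8 h arrays or 72 h replicate 1 (highest adjusted p = 0.089 and 0.23), and without 8 h replicate 2 the number of genes that fell was 2.

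Known targets of VDR were higher as a list at 8 h, through part of its members. Of 23 tested targets, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 4.2e-15; adjusted p = 4.8e-04 with an estimated correlation). They were CYP24A1, CAMP, DUSP10, GADD45A, the secreted protease KLK6 (1.39), and, chosen after their values were seen, G0S2 (0.88), NRIP1 (0.86) and SERPINB1 (0.65). The list's median log2 change was 0.21 and its mean 0.71, so large rises of a few members carry much of the mean. On the U95 arrays 12 of 19 members were positive at 8 h, with a median of 0.51. GADD45A was picked by the study from its own arrays, so its place in the list is not independent evidence. Of 12 genes of vitamin D metabolism and the receptor complex, CYP24A1 alone passed, over all genes as over the list alone (camera adjusted p = 0.12; 0.032 without vehicle replicate 1). Among 26 p53 targets, GADD45A and GADD45B (0.83) rose and 0 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.22 with an estimated correlation). Among 26 ovarian carcinoma markers, the transcription factor WT1 (0.97, from a signal of 2095 ± 156 to 4102 ± 197) and KLK6 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.028; adjusted p = 0.35 with an estimated correlation). The p53 call ended without 8 h replicate 1 (adjusted p = 0.075), and the marker call without vehicle replicate 1 or 3 or 8 h replicate 2 (highest adjusted p = 0.16) and with quantile normalization (adjusted p = 0.13). The call of GADD45B ended without any 1 of the vehicle arrays, 8 h replicate 1 or 2 or 24 h replicate 1 (highest adjusted p = 0.22), and NRIP1 without any 1 of the vehicle and 8 h arrays (0.19) and with median centring; both ended with the mean of a gene's probe sets.

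Another 5 lists were called by camera at 8 h, with small shifts of members that did not pass singly. Such list calls are weak evidence. Other splits of the 6 arrays compared called up to 7, 9 and 8 lists at 8, 24 and 72 h, against 8, 9 and 6 in the real splits. The ribosomal proteins were higher, with 40 of 40 members positive and a median log2 change of 0.12 (camera adjusted p = 9.8e-10; adjusted p = 0.35 with an estimated correlation). With quantile normalization that call ended (adjusted p = 0.12). Mitosis genes were lower, with 31 of 41 negative and a median of -0.09 (camera adjusted p = 0.0036; adjusted p = 0.35 with an estimated correlation), and so were interferon response genes, with 24 of 30 negative and a median of -0.12 (camera adjusted p = 0.0036; adjusted p = 0.22 with an estimated correlation). Among these, DLGAP5, a spindle protein, had -0.37 and the guanylate binding protein GBP1 -0.76, neither past the test (GBP1 passed with a replicate block, adjusted p = 0.025). G1 phase regulators (16 of 21 negative, median -0.08) and cholesterol synthesis genes (12 of 20 negative, median -0.08) were lower with camera adjusted p = 0.045 and 0.040 (adjusted p = 0.35 and 0.34 with an estimated correlation). In each of these lists 0 members passed, over all genes or over the list alone. The mitosis call ended without vehicle replicate 1 or 8 h replicate 2 (highest adjusted p = 0.18) and the G1 call without vehicle replicate 1 or 3 or 8 h replicate 1 or 2 (0.37). The cholesterol call ended without vehicle replicate 3 or 8 h replicate 1 or 2 (0.21), with quantile normalization (adjusted p = 0.081) and with a replicate block (adjusted p = 0.051).

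After 24 h, CCL20 and RGCC were lower than in vehicle and CYP24A1, CAMP and GADD45A higher. CCL20, a chemokine that attracts lymphocytes and dendritic cells, fell from a signal of 863 ± 169 to a mean of 37.5, with arrays between 28.0 and 49.5 (log2 change -4.04, SE 0.34, adjusted p = 1.9e-06). RGCC was down to 172 ± 67.0 (-2.92, adjusted p = 2.0e-07). CYP24A1 reached 7330 ± 1883, 57.9-fold over vehicle, CAMP 896 ± 103 (log2 change 4.29) and GADD45A 1800 ± 264 (3.76-fold, adjusted p = 7.5e-07). WNT11, a secreted ligand of the Wnt family, rose from 34.2 ± 12.6, near background, to 430.0 ± 91.8 (log2 change 3.17, or 3.66 and 2.33 with the other pseudocounts, adjusted p = 3.8e-07), and the protease KLK6 rose 5.61-fold from 829 ± 67.8 to 4754 ± 736. VDR stood at 473 ± 39.6 and did not pass (log2 change 0.19, adjusted p = 0.62).

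The counts at 24 h were 176 genes higher and 116 lower, 45 and 23 of them by at least 2-fold. Other large rises were the protease inhibitor SERPINB7 (log2 change 3.04), PALMD (2.44), DUSP10 (2.08), SECTM1 (2.06), CALCB (2.03) and the secreted TSKU (1.91). Other large falls were the neutrophil chemokines CXCL2 (-1.89), CXCL3 (-1.62) and CXCL6 (-1.37), the cytokine IL6 (-1.35), FAM107A (-1.63), the keratin KRT23 (-1.59), the membrane protein MAL (-1.37) and the calcium-binding S100A8 (-1.35). The number that fell was 65, 75 or 69 without vehicle replicate 1, 2 or 3, 77 without 24 h replicate 1, and 72 with median centring. It was 188 with a replicate block.

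The NF-kappaB and cytokine list was lower at 24 h, with 8 of 25 tested members down, 1 up and 16 not past the test, or 9 and 1 adjusted over the list alone (camera adjusted p = 4.9e-06; adjusted p = 0.22 with an estimated correlation). Beside the genes above, CXCL8, also called interleukin 8, fell by 1.24 on the log2 scale from a signal of 2476 to 1032, and, chosen after their values were seen, CXCL1 (-0.90) and the NF-kappaB inhibitor TNFAIP3 (-0.67) fell. CSF1, the growth factor of macrophages, rose (1.27) on the only 1 of its 4 probe sets above the filter. The probe sets ranged from -0.18 to 1.27, and the U95 ratio was negative (-0.68). In the interferon list 3 of 30 fell and 0 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 3.0e-04; adjusted p = 0.17 with an estimated correlation). These were GBP2 (adjusted p = 0.0050), IRF1 (-0.53) and IFITM3 (-0.35). The calls of IRF1 and IFITM3 ended without vehicle replicate 2 or 3 or 24 h replicate 3, that of IRF1 also without vehicle replicate 1 or 24 h replicate 1 or 2 (highest adjusted p = 0.13 and 0.0997), and IFITM3 with median centring.

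The mitosis, G1 phase and DNA replication lists were lower at 24 h by camera at the preset correlation, but none passed with an estimated correlation. The G1 list mixes cyclins and kinases with inhibitors, so its shift gives no direction of the cycle. Of 41 mitosis genes 40 were negative, with a median log2 change of -0.22, and 5 passed, or 11 adjusted over the list alone, with 0 up in either count (camera adjusted p = 1.7e-10; adjusted p = 0.18 with an estimated correlation). They were the phosphatase CDC25B (-0.71, from a signal of 1993 ± 35.5 to 1219 ± 115), the kinesins KIF11 (-0.51) and KIF20A (-0.46), the centromere histone CENPA (-0.47) and, chosen after its value was seen, DLGAP5 (-0.36). Of 21 G1 phase regulators 19 were negative and 0 passed in either count (camera adjusted p = 0.0088; adjusted p = 0.28 with an estimated correlation). Of 37 DNA replication genes, MCM10, a replication factor, fell (-0.64), 1 in either count (camera adjusted p = 0.0498; adjusted p = 0.34 with an estimated correlation). KIF11, KIF20A and CENPA lost their calls with median centring and without vehicle replicate 1 (highest adjusted p = 0.062, 0.17 and 0.097), KIF20A and CENPA also without vehicle replicate 2 or 3 or 24 h replicate 2, CENPA without 24 h replicate 3, KIF20A without 8 h replicate 2, and MCM10 lost its call without vehicle replicate 1 or 24 h replicate 3 (0.095). The G1 call ended without vehicle replicate 3 or 24 h replicate 1 (0.058), and the replication call with quantile normalization (adjusted p = 0.053), median centring (0.080) or without any 1 of the vehicle arrays, 8 h replicate 2 or 3, 24 h replicate 1 or 2 or 72 h replicate 2 (highest 0.15).

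Among VDR targets 11 of 23 had risen and 1 had fallen at 24 h, the same numbers adjusted over the list alone (camera adjusted p = 2.8e-12; adjusted p = 0.0010 with an estimated correlation). S100A8 was the member that fell. Glycolysis and hypoxia genes were higher, with 4 of 28 up and 0 down, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.51 with an estimated correlation). These were the glycolytic enzyme PFKP (0.66), the vasoactive peptide ADM (0.91), the angiogenic factor VEGFA (0.58) and NDRG1 (0.64). This list call ended without vehicle replicate 1 or 3 or 24 h replicate 2 (highest adjusted p = 0.30) and with quantile normalization (0.27), the VEGFA call without vehicle replicate 3 or 24 h replicate 1 (0.053) and with the mean of its probe sets, and the NDRG1 call without vehicle replicate 1 or 3, 8 h replicate 2 or 24 h replicate 1 or 2 (0.19) and with median centring. Ribosomal proteins had 39 of 40 members positive with a median of 0.15 (camera adjusted p = 5.2e-08; adjusted p = 0.45 with an estimated correlation) and mitochondrial respiration genes 32 of 40 (camera adjusted p = 0.035; adjusted p = 0.67 with an estimated correlation), with 0 members past the test in either count. With quantile normalization both calls ended (adjusted p = 0.55 and 0.52), and the respiration call also ended without vehicle replicate 1 or 3 or 24 h replicate 1 (highest adjusted p = 0.66).

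After 72 h, WNT11 and FLG were higher than at 24 h. WNT11 reached a signal of 1165 ± 205 (log2 change 4.58 against vehicle, or 5.11 and 3.65 with the other pseudocounts, adjusted p = 4.3e-09), and SERPINB7 1086 (4.11). FLG, the epidermal protein filaggrin, rose 5.15-fold from 1093 to 5702 (adjusted p = 3.9e-08), and TRPV6, the calcium channel of absorbing epithelia, rose from 76.2 to 389 (log2 change 2.29, adjusted p = 0.0012). CYP24A1 stood at 7430 ± 1407 (59.4-fold), CAMP at 1138 ± 117 (log2 change 4.63) and GADD45A at 1943 ± 296 (4.06-fold, adjusted p = 3.2e-07). CCL20 was at 61.1 ± 47.1, a log2 change of -3.66 (adjusted p = 4.4e-06). VDR was at 337 ± 30.7 and did not pass (-0.28, adjusted p = 0.30).

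At this time 277 genes were higher and 214 lower, 77 and 39 of them by at least 2-fold. The other large rises were KLK6 (log2 change 2.85), PALMD (2.61), CALCB (2.52) and the cytoskeletal regulator DPYSL3 (2.36). Large falls were FAM107A (-2.40), RGCC (-2.33), S100A8 (-2.29), KRT23 (-2.02), the immune checkpoint ligand VTCN1 (-1.95), MAL (-1.86), TMEM100 (-1.73), CXCL2 (-1.69) and LTBP1, which binds latent TGF-beta (-1.61). The number that fell was 119, 142 or 130 without vehicle replicate 1, 2 or 3.

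Interferon response genes were lower at 72 h, with 8 of 30 down and 1 up, or 12 and 1 adjusted over the list alone (camera adjusted p = 9.6e-04; adjusted p = 0.24 with an estimated correlation). The antiviral membrane proteins IFITM1 (-1.51), IFITM2 (-0.73) and IFITM3 (-0.44) fell, as did TRIM22 (-0.76), a restriction factor of viruses. Of the NF-kappaB and cytokine list 6 of 25 were down and 2 up, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.39 with an estimated correlation). CCL20, CXCL2 and CXCL6 (-1.35) fell and CSF1 rose (1.31, with its probe sets from -0.62 to 1.31). This call ended without vehicle replicate 3 or 72 h replicate 2 (highest adjusted p = 0.13).

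Glycolysis and hypoxia genes were higher at 72 h, with 24 of 28 positive, a median log2 change of 0.26, 4 up and 1 down, or 15 and 2 adjusted over the list alone (camera adjusted p = 1.8e-06; adjusted p = 0.39 with an estimated correlation). PFKP (1.01), ADM (0.98), VEGFA (0.67) and the enzyme TPI1 (0.34) rose, and PFKFB3 (-0.59), named after its value was seen, fell. Mitosis genes were lower, with 36 of 41 negative (camera adjusted p = 5.6e-04; adjusted p = 0.39 with an estimated correlation). CDC25B (-0.54) and DLGAP5 (-0.42) fell and 0 rose, the same numbers adjusted over the list alone. Among VDR targets 10 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 7.1e-09; adjusted p = 0.0033 with an estimated correlation). Ribosomal proteins had 36 of 40 members positive and 0 past the test in either count (camera adjusted p = 6.2e-05; adjusted p = 0.58 with an estimated correlation). The mitosis call ended without 72 h replicate 2 (adjusted p = 0.0501), that of DLGAP5 without vehicle replicate 2 or 3 (highest 0.057), and that of TPI1 without vehicle replicate 1 or 3 or 72 h replicate 1 or 2 (0.100), with median centring and with the mean of its probe sets. The ribosomal call ended without vehicle replicate 1 (adjusted p = 0.094), and with quantile normalization the mean change of that list reversed from 0.13 to -0.0087 (adjusted p = 0.86).

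**Figure D1:**
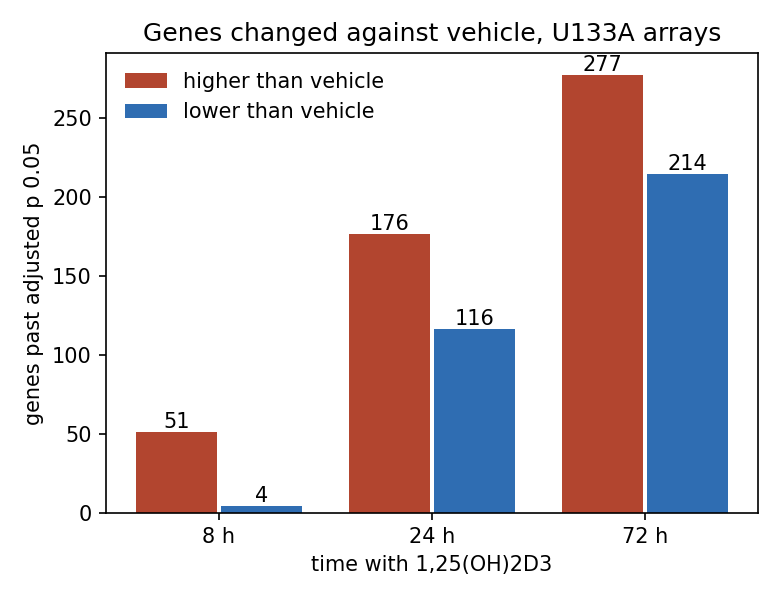
Genes past an adjusted p of 0.05 against vehicle at each time on the U133A arrays, in bars from 0, higher and lower genes apart. The counts run from 51 and 4 at 8 h through 176 and 116 at 24 h to 277 and 214 at 72 h.

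**Figure D2:**
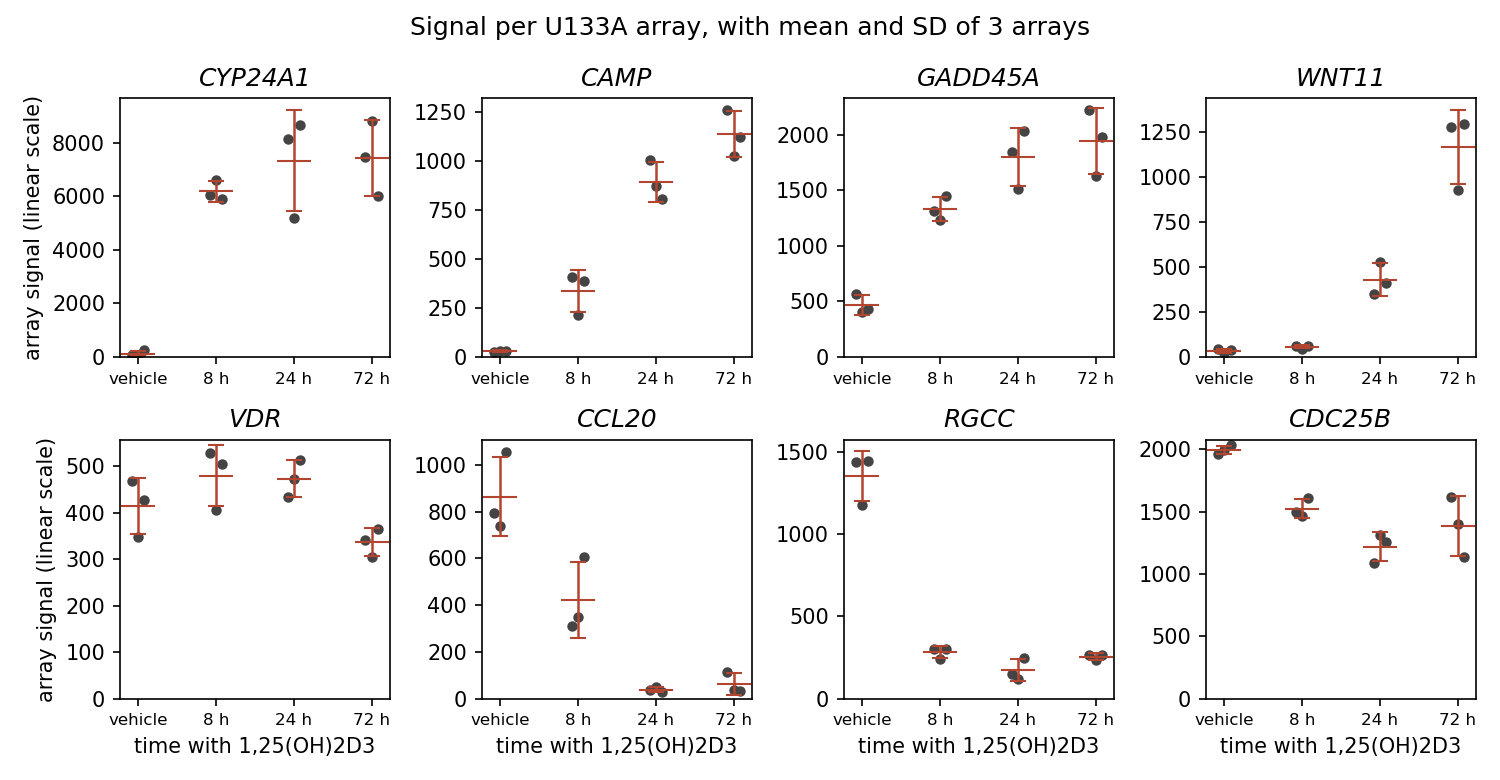
Signal on the deposited linear scale of 8 genes in vehicle and after 8, 24 and 72 h, with a dot for each of the 3 U133A arrays of a group and the mean with its SD. CYP24A1, CAMP, GADD45A and WNT11 lie above vehicle at 72 h, CCL20, RGCC and CDC25B lie below it, and VDR did not pass the test at any time.

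The early genes stayed changed. Of the 51 genes higher at 8 h, 49 were among those higher at 24 h and 48 among those higher at 72 h, and 48 were higher at all 3 times, among them CYP24A1, CAMP, GADD45A, KLK6 and WT1. All 4 genes lower at 8 h, RGCC, IRF8, ADAMTS1 and LMCD1, were lower at all 3 times. Calls at 24 and 72 h shared 148 higher and 80 lower genes, and 0 genes were called in opposite directions. Independent lists would share 1.25, 1.97 and 6.79 higher genes for 8 and 24 h, 8 and 72 h, and 24 and 72 h. Simulations of unchanged groups with the shared vehicle arrays called almost no genes and shared at most 1. When as many genes as were called were instead taken by rank from each simulation, a comparison chosen after the data were seen, the 3 shared vehicle arrays alone gave a mean of 17.9, 21.5 and 53.8 shared higher genes (at most 30, 31 and 70) and 34.6 shared lower genes for 24 and 72 h (at most 45), and they gave up to 4 of the 4 lower at 8 h. Part of the overlap may therefore come from the shared vehicle arrays. An F test called 374 genes changed at any time, and 201 were higher and 123 lower in the mean of the treated groups. Without vehicle replicate 3 the latter came to 196 in all.

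Direct contrasts between times gave 26 genes higher and 20 lower at 24 h than at 8 h. WNT11 was higher (log2 difference 2.61, SE 0.23, adjusted p = 5.6e-05), with SERPINB7 (2.27), KLK6 (1.10), the BMP antagonist CHRDL1 (1.01) and the actin-binding ABLIM1 (0.83). CCL20 was lower (-3.00, adjusted p = 4.8e-04), with CXCL2, MAL, LTBP1 and the proteoglycan SDC4. From 24 to 72 h, 6 genes were higher, with the lowest p for CCNA1, a cyclin (1.56, adjusted p = 9.9e-04), and FLG (1.08), and 5 lower, with the lowest p for the fibrillin FBN2 (-0.80). From 8 to 72 h, 99 were higher, with the lowest p for WNT11 (4.02, adjusted p = 1.2e-07), and 82 lower, with the lowest p for FBN2 (-1.35). With a replicate block, the 46, 11 and 181 genes that differed from 8 to 24 h, 24 to 72 h and 8 to 72 h became 90, 25 and 292, and all of the 46, 11 and 181 were among them. The difference between 24 and 8 h was called for 25, 20 or 11 genes without 8 h replicate 1, 2 or 3 and for 22, 29 or 25 without 24 h replicate 1, 2 or 3, and that between 72 and 8 h for 108 or 103 without 8 h replicate 2 or 3 and 120 without 72 h replicate 1. The difference between 72 and 24 h was called for 7, 7 or 6 genes without vehicle replicate 1, 2 or 3, 6, 6 or 7 without 8 h replicate 1, 2 or 3, 5, 4 or 6 without 24 h replicate 1, 2 or 3 and 4 without 72 h replicate 3.

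The U95 arrays covered the same times in the study's initial set, without replicates, so that every ratio rests on 1 vehicle array. The log2 ratio of 3' to 5' control probe sets for GAPDH was -2.62 on that array and -1.96, -0.88 and -1.65 at 8, 24 and 72 h, and for ACTB it was -0.36 and -0.46, -0.30 and 0.14. CYP24A1 went from a signal of 15.3 in vehicle to 1395, 1776 and 1919 at 8, 24 and 72 h, and GADD45A from 383 to 793, 950 and 921 (log2 ratios 1.02, 1.28 and 1.24). CAMP had log2 ratios of 1.53, 2.92 and 2.79, KLK6 of 0.74, 1.54 and 1.86, WNT11 of 0.32, 0.62 and 0.84, and CCL20 of -0.52, -1.59 and -1.20. VDR had -0.10, -0.26 and -0.69. Of U133A genes higher at 8, 24 and 72 h and measured on both types, 34 of 36, 118 of 132 and 179 of 202 had the same sign. Of those lower at 24 and 72 h, 94.2% and 94.0% did, and none of the 4 lower at 8 h was above the filter on both. Of all 4167 genes, 47.9%, 47.4% and 44.5% had a positive U95 ratio at 8, 24 and 72 h. A negative ratio was found for 52.6% and 55.5% at 24 and 72 h. The medians of these sets of calls lay beyond all 10000 matched random sets, which hold no spread between arrays, at 0.68, 0.55 and 0.56 for higher and -0.56 and -0.55 for lower genes. Across the 4167 genes Pearson's r was 0.37, 0.47 and 0.56, as a description only, since genes are not independent replicates. Of the 23 calls of lists on U133A, 20 had a U95 median of the same sign and 3 of the opposite sign. Many of these calls are of the same list at different times, and all share 1 U95 vehicle array, so they are not independent. Mitosis genes had medians at percentiles 0.69, 1.15 and 4.66 of matched sets, and glycolysis and hypoxia genes at 72 h at percentile 100, with 22 of 26 positive. NF-kappaB and cytokine genes had medians at percentiles 86.74, 6.74 and 0.27. The interferon list had positive medians at 8 h (0.11, percentile 97.95) and 24 h (0.030, percentile 81.35, 13 of 21 positive), opposite in sign to U133A, and a negative one at 72 h (-0.13, percentile 28.98). The p53 list at 8 h was also opposite (-0.07, percentile 33.63, 8 of 20 positive), and the ovarian marker list lay at percentiles 42.14, 99.99 and 99.94 at the 3 times, with 19 of 24 positive at 72 h. Of 40 ribosomal proteins 36, 23 and 37 were positive, with medians at percentiles 98.85, 82.6 and 100.

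**Figure D3:**
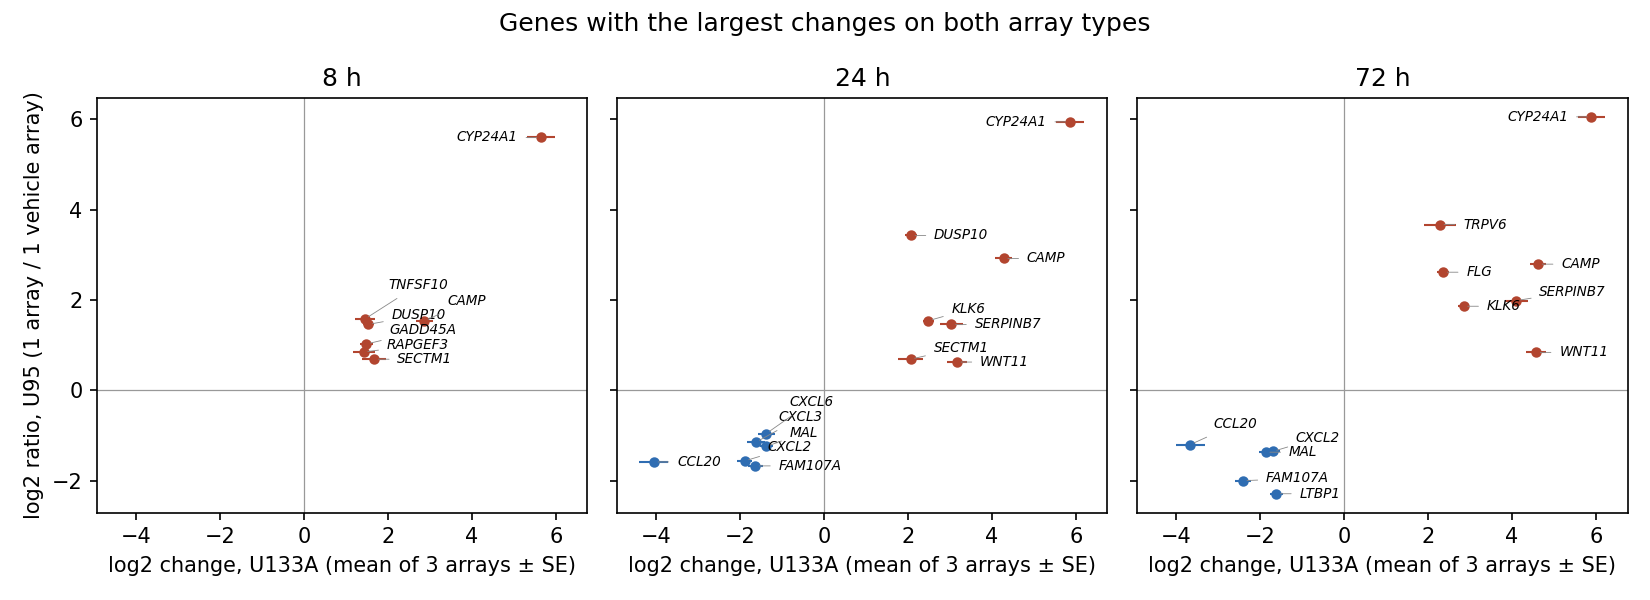
Log2 change on U133A (mean of 3 arrays, bars SE) against the log2 ratio of single U95 arrays for the genes with the largest changes that were measured on both types, 7 at 8 h, 13 at 24 h and 12 at 72 h. Every one of these genes has the same sign on both axes.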

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

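The tests of scaling, of single arrays and of the U95 arrays and the splits with a replicate block below were chosen only after the results were seen, while the other splits of the samples were planned.

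The response to the hormone differed between times by direct test. From 8 to 24 h, 46 genes differed. Those with the lowest p were WNT11 (log2 difference 2.61), CHRDL1 (1.01), ABLIM1 (0.83), SERPINB7 (2.27) and KLK6 (1.10) upward, and CCL20 (-3.00), MAL (-1.09), LTBP1 (-1.05), CXCL2 (-1.17) and SDC4 (-0.58) downward. From 24 to 72 h, 11 differed, namely CCNA1 (1.56), FLG (1.08), TUBA1A (0.91), SLC39A8 (0.70) and WNT11 (1.41) among the higher, and FBN2 (-0.80), GPNMB (-1.18), USP48 (-0.75), LCN2 (-0.92) and SIM1 (-0.63) as the lower genes. From 8 to 72 h, 181 differed, with WNT11 (4.02), CHRDL1 (1.38), FLG (1.95), ABLIM1 (1.09) and SERPINB7 (3.33) upward and FBN2 (-1.35), MAL (-1.58), FAM107A (-1.76), LTBP1 (-1.40) and LCN2 (-1.54) downward.

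Signals also appeared in 1256 probe sets that the comparisons leave out because they have no single gene name. By the same test, 3 of them differed from vehicle at 8 h, 24 at 24 h and 54 at 72 h.

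Other splits of the arrays were counted for each comparison. For 1 time against another group, 10 splits of the 6 arrays exist, too few for a share under 0.05. The real split called 55 genes at 8 h, and the highest other split 1. At 24 and 72 h the real splits called 292 and 491 genes, and the highest other split 0. Between times the real splits called 46, 11 and 181 genes, and the highest others 0, 3 and 1, so that in each of these 6 comparisons 1 split gave as many. Splits with a replicate block were counted only from 8 to 24 h and from 24 to 72 h, where all 3 same-number pairs correlated over 0.1. In each, 4 of the 10 splits part all 3 pairs. With a replicate block, the real splits called 90 and 25 genes and the highest other of these 4 called 0 in both, and the remaining splits leave pairs together. For gene lists, 1, 2 and 3 splits gave as many calls as the real ones at 8, 24 and 72 h, with 8, 9 and 6 lists in the real splits and up to 7, 9 and 8 in the others. Among 100 regroupings of the 12 arrays, 1, the real grouping, gave as many genes changed at any time (374, highest other 89). The same held for genes changed in the mean of treated arrays (324, highest other 10). This is the smallest share that 100 regroupings can give. The regroupings moved arrays freely across replicate numbers, so they take no account of a pairing by number. The share argues against chance for both only if the numbers do not pair the arrays.

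NF-kappaB and cytokine genes were lower at 24 h, with a mean log2 change of -0.55. Scaling that depends on signal is argued against, since genes matched on signal showed 2.77% of that change, quantile normalization left a mean of -0.54, and 0 of 10000 matched random lists were as extreme. A single array is argued against too, as the list's mean stayed between -0.60 and -0.48 with 1 array left out. The highest camera adjusted p of these fits was 6.27e-05. On the U95 arrays the list's median lay at percentile 6.74 of matched lists, and its mean at percentile 0.53 of lists matched on signal more closely. Single arrays hold no spread, so a change particular to the U133A experiments cannot be told apart from a general one. A response to 24 h of 1,25(OH)2D3 may account for the fall and stays open, with the limit that the adjusted p with an estimated correlation was 0.22.

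Mitosis genes were lower at 24 h, with a mean log2 change of -0.26 over 41 genes. Genes matched on signal moved the other way, by -4.84% of the list's mean, which argues against scaling, and quantile normalization left -0.26. With 1 array left out, the list's mean stayed between -0.29 and -0.21, which argues against a single array. The highest camera adjusted p of these fits was 6.98e-07. On the U95 arrays the median lay at percentile 1.15 of matched lists, but with 1 array for each time a change particular to the U133A experiments cannot be told apart from a general one. A response to 24 h of 1,25(OH)2D3 may account for the fall and stays open, with the limit that the adjusted p with an estimated correlation was 0.18. No measure of proliferation was tested.

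Ribosomal protein genes had mean log2 changes of 0.13, 0.14 and 0.13 at 8, 24 and 72 h. Genes outside the list matched on signal showed 73.6%, 96.2% and 106% of these means, and quantile normalization left 0.030, 0.013 and -0.0087, so scaling that depends on signal is a candidate explanation of the U133A values. Of 10000 matched random lists, 155, 3948 and 5971 had means as high, so at 8 h the list lay beyond most matched lists on U133A. That count compares genes with genes and holds no spread between arrays. It cannot show whether scaling by signal leaves part of the rise at 8 h unaccounted for. On the U95 arrays, 1 for each time against 1 vehicle array, the list rose beyond its matched genes. There the matched genes showed 28.5%, 25.5% and 22.7% of the list's mean, quantile normalization left 76.2%, 84.5% and 72.1% of it, and the mean lay at percentiles 100, 98.56 and 100 of matched lists. These single arrays exclude nothing, so scaling of the U133A arrays cannot be told apart from a rise of the list itself. The U95 medians lay at percentiles 98.85, 82.6 and 100 at 8, 24 and 72 h, and for want of replicates a change particular to the U133A experiments stays open as well. With 1 array left out, the list's mean came down to as little as 0.054, 0.071 and 0.052 at 8, 24 and 72 h. A single array may therefore account for much of the rise and is not argued against. The camera call itself held at 8 and 24 h, where the highest adjusted p with 1 array left out was 0.020 and 0.00452. At 72 h it did not, with 0.0942 without vehicle replicate 1. A response to the hormone stays open.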

How the results depend on the processing

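No test of this part was chosen only after the result was seen. Of the values of counts under the alternatives, 176 stayed within 1.5 times and 67 did not. Of the values of single genes and lists, 3279 kept their direction and side of the threshold, 70 passed that had not, 118 no longer passed and 1 reversed. That tally of genes and lists does not hold the fits with 1 array left out, whose losses are given apart and are more numerous. Of 159 calls of named genes, quantile normalization kept 158, median centring 140, a pseudocount of 1 kept 157 of 157, a pseudocount of 4 times the 10th percentile 159, the mean of probe sets 137 of 155, and leaving out 1 array kept 125 to 151, with 42 lost without some array. With quantile normalization 55 of 55, 273 of 292 and 482 of 491 genes were called again at 8, 24 and 72 h. Signal over background limits genes near the pseudocount, such as CCL20 at 24 h. With a pseudocount of 1, CCL20 had no value at 24 or 72 h and is not among the 157. With 4 times the 10th percentile its log2 changes were -3.19 and -2.94.

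The following counts moved by over 1.5 times, and the cause was not tested except where the setting itself calls fewer genes. Without probe sets of the x and s type, which leaves fewer genes, 32, 116 and 164 genes were higher at 8, 24 and 72 h, 73 and 135 lower at 24 and 72 h, 236 changed at any time, 205 in the treated mean, and 21, 6 and 108 differed between 24 and 8 h, 72 and 24 h, and 72 and 8 h. With a log2 change of at least 1, which is stricter by construction, the higher genes were 17, 45 and 77, the lower 2, 23 and 39, those at any time 119, in the treated mean 60, and between times 10, 4 and 45. At an adjusted p of 0.1, looser by construction, the lower genes were 10, 185 and 325, those differing between 72 and 8 h 282, and the lower genes shared by 8 and 24 h, 8 and 72 h, and 24 and 72 h were 8, 8 and 121.

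Genes lower at 8 h, 4 in the fit reported, were 7 with 4 times the pseudocount, 2 with a filter at the 60th percentile, 7 with the mean of probe sets, 8 without trend, 12 with array weights and 16 with only the groups compared. Genes lower at 24 h were 72 with median centring and 201 with array weights. The difference between 24 and 8 h called 28 with median centring, 22 without a filter and 27 without trend. That between 72 and 24 h called 6 with quantile normalization, 5 with median centring, 4 without a filter, 7 with every probe set, 5 with the mean of probe sets, 4 without trend and 5 with only the groups compared. Only the groups compared gives no value of its own for any time and the treated mean, which use all groups. Lists called were 1, 1 and 1 at 8, 24 and 72 h with an estimated correlation, 3 with fry at 8 h, and 5 and 5 with quantile normalization at 8 and 24 h. Ribosomal proteins at 72 h reversed with quantile normalization, to a mean of -0.0087 (adjusted p = 0.86; range over its other adjusted p values with 1 array left out 2.5e-11 to 0.094).

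Leaving out 1 array gave 34 to 54 genes higher and 2 to 6 lower at 8 h, 120 to 189 and 65 to 129 at 24 h, 194 to 300 and 119 to 231 at 72 h, 261 to 401 at any time and 196 to 354 in the treated mean. Between times it gave 11 to 49, 4 to 13 and 103 to 204, and 4 to 12, 5 to 11 and 5 to 10 lists at 8, 24 and 72 h.

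The labels do not say whether arrays with the same replicate number share an experiment. The U133A arrays came from independent experiments, with vehicle and treated cells harvested together, so equal numbers may mark the same experiment. The counts of the fit reported leave such a pairing out. Of 18 pairs of arrays with the same number, 12 deviated together with a correlation over 0.1 (range 0.052 to 0.26, mean 0.12). Among them were all pairs from 8 to 24 h and from 24 to 72 h. The mean of -0.062 for unlike numbers follows largely from taking deviations from group means and adds no evidence. All 12 arrays correlated best with 1 of their own number, a hint from the data. With a replicate block, 69 genes were higher and 15 lower at 8 h, 232 and 188 at 24 h, 362 and 291 at 72 h, 534 at any time, 437 in the treated mean, 90, 25 and 292 between times, and 7, 11 and 7 lists were called. All 159 calls of named genes passed with the block. Among lists it ended the cholesterol call at 8 h and added the insulin-like growth factor axis at 24 and 72 h (adjusted p = 0.048 and 0.030) and the unfolded protein response at 24 h (0.04999), and it changed no other list call.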

Other observations

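The order-within-signal shuffle of neighbouring genes below was chosen only after the result was seen, while the other tests of this part were planned.

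Single members of further lists rose or fell at 72 h, and these lists did not pass in the fit reported. For comparison, 491 of all 7178 tested genes were called at that time. Of 25 tested TGF-beta genes 6 rose and 3 fell, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.75). FST, an antagonist of activins (log2 change 1.16), and the activin subunit INHBB (0.99) rose, and LTBP1 (-1.61) and the receptor TGFBR2 (-0.84) fell. Of 23 genes of epithelial junctions and Wnt 4 rose and 1 fell, or 4 and 2 over the list alone (camera adjusted p = 0.33), with the adherens junction protein CDH1 (0.69), the desmosome protein PKP2 (0.78) and TCF7L2 (0.46, but -0.17 on U95) up and WNT5A (-0.52) down. Of 26 ovarian carcinoma markers 7 rose and 3 fell at 72 h, or 11 and 5 over the list alone (camera adjusted p = 0.061, but past the test without vehicle replicate 2 or 72 h replicate 3, lowest 0.0091), with KLK6, WT1 (1.05), MAL and LCN2 (-1.56) the clearest. Of 10 keratin and squamous genes 1 rose, FLG, and 3 fell, S100A8, SFN (-0.44) and TGM2 (-0.52), or 2 and 4 over the list alone (camera adjusted p = 0.51). Among 12 genes of the insulin-like growth factor axis IGFBP4 (0.90) and IGFBP2 (0.68) rose and IRS2 (-0.39) fell, or 3 and 1 over the list alone (camera adjusted p = 0.069, but 0.030 with a replicate block, and past the test without vehicle replicate 1 or 72 h replicate 2, lowest 0.026). Among 18 mesenchymal and invasion genes the urokinase receptor PLAUR (0.75) and the matrix protein FN1 (2.11) rose and TNC (-1.22) fell, the same numbers over the list alone (camera adjusted p = 0.51). EGFR, the only one of 14 genes of its family past the test, fell (-0.84), or 2 lower over the list alone (camera adjusted p = 0.30).

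Genes of cell death and stress moved singly at 72 h. As 491 of all 7178 tested genes were called at that time, several counts below lie near the share of any list. Of 16 death receptor genes TNFSF10 (1.21) and the adaptor TRADD (0.58) rose and the receptor FAS (-1.22) fell, the same numbers over the list alone (camera adjusted p = 0.80). Of 17 mitochondrial apoptosis genes 0 passed, or 4 up and 1 down over the list alone (camera adjusted p = 0.29). Of 26 p53 targets 6 rose and 1, FAS, fell, or 7 and 1 over the list alone (camera adjusted p = 0.16), with DDIT4 (1.10), an inhibitor of mTOR signalling, and PHLDA3 (0.94) beside GADD45A. Of 20 immediate early genes 4 rose and 2 fell, or 5 and 3 over the list alone (camera adjusted p = 0.51), with FOSL2 (1.30) up and KLF4 (-0.97) down. Of 26 genes of the unfolded protein response CEBPB (0.72) rose and EIF2AK3 (-0.49) fell, or 4 and 1 over the list alone (camera adjusted p = 0.29). Of 34 oxidative stress genes TXNRD1 (0.60), GSTM3 (0.50) and GCLC (0.46) rose, the same number over the list alone (camera adjusted p = 0.096; 0.049 without 72 h replicate 3), but GSTM3 had -0.60 on U95. The chaperone CRYAB fell (-0.99) among 16 heat shock genes (camera adjusted p = 0.51), TM7SF2 rose (0.89) among 20 of cholesterol synthesis (0.96), and NRIP1 rose (1.18) among 13 steroid receptor genes (0.83), each the only one over the list alone as well. Of 20 fatty acid genes and 26 proteasome genes 0 passed in either count (camera adjusted p = 0.52 and 0.56), and of 40 respiration genes SDHA (0.54) and NDUFB5 (0.31) rose (camera adjusted p = 0.069, but past the test without vehicle replicate 2 or 72 h replicate 3, lowest 0.0013).

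Several of these single calls rest on particular arrays or settings. WNT5A and EGFR lost theirs without vehicle replicate 1 (adjusted p = 0.062 and 0.061), SFN without vehicle replicate 2 or 3 (highest 0.062), TRADD without vehicle replicate 1 or 2 or 72 h replicate 1 (0.084), FN1 without vehicle replicate 2 or 3 or 72 h replicate 1 (0.088), EIF2AK3 without the same arrays (0.093), and IGFBP2 without vehicle replicate 2 or 3 or 72 h replicate 1 or 2 (0.14). NDUFB5 lost it without vehicle replicate 1 or 3 or 72 h replicate 1 or 2 (0.13), SDHA also without 72 h replicate 3 (0.13), GCLC without vehicle replicate 2 or 3 or any 72 h replicate (0.15), TGM2 without vehicle replicate 1 or 3, 8 h replicate 1, 24 h replicate 1 or any 72 h replicate (0.17), and IRS2 without any 1 of 9 arrays, those other than 8 h replicate 2, 24 h replicate 2 and 72 h replicate 3 (0.17). With median centring GCLC, IGFBP2, IRS2, NDUFB5 and TGM2 no longer passed, and with the mean of probe sets EGFR, IRS2, SFN, TCF7L2, TGM2, TNC and TRADD did not.

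A hypothesis of this re-analysis was that genes next to one another in the genome change together at 72 h. Genes were taken as adjacent where no other tested gene lay between them, whatever the distance. Genes that were not tested may lie between the members of a pair. Among 7176 tested genes placed in order, 45 adjacent pairs were both called in the same direction, against a mean of 17.0 and at most 33 in 10000 shuffles of the calls (one-sided permutation p = 0.0001, the smallest the shuffles can give). With pairs whose names share their first letters left out, 34 pairs remained, against a mean of 16.5 and at most 33 (one-sided permutation p = 0.0001, likewise the smallest). Shuffles within 20 bins of signal gave at most 34 in either case (one-sided permutation p = 0.0001 and 0.0002). Pairs chosen after their values were seen include KLK7 (1.09) with KLK8 (0.69), COL4A1 (1.67) with COL4A2 (1.51), CITED2 (1.08) with HIVEP2 (1.19) and RAB38 (1.50) with CTSC (0.95). The counts are in line with neighbouring genes sharing part of the response, which may also include duplicated genes whose names differ or probe sets that read more than 1 gene, neither of which was tested.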
